A study of Drosophila melanogaster with 6 samples.

How the data were processed

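RNA selected for poly(A) tails was measured in 6 libraries of Drosophila melanogaster cells, 4 of S2-DRSC cells and 2 of S2-DRSC cells stably transfected with HA-tagged AbdA, all treated with 10 µM copper sulphate for 24 h per the labels. Each library's group was taken from its title and its replicate number from the same title. Replicates 3 and 4 of S2 differ from replicates 1 and 2 in that their descriptions do not name the authors' table of changed genes.

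The authors deposited 1 table of raw counts per gene and library, not normalized, in which each gene carries a symbol, an NCBI gene number and a chromosome, start and end. CASAVA, edgeR and the build dm3 are named in the submitters' processing notes, without versions. The aligner, the counter, the annotation release, the strand setting and the read layout are not given in the sources used here. Without a known strand setting, overlapping genes and antisense genes cannot be told apart, and members of gene families with near-identical copies are uncertain. The authors also deposited a table of 2122 genes with 2 columns of log2 values and columns of p-values and false discovery rates (FDR), every FDR under 0.10. Per the file headers 1 of the log2 columns is a log fold change and the other a log concentration, but set against the counts the headings were found to be exchanged, and the ratio was found to be S2 over S2-AbdA. The correlation across genes between the column headed logConc and the log2 ratio of S2-AbdA over S2 replicates 1 and 2 was -0.942 (pseudocount 0.1 CPM), and that between the column headed logFC and the mean log2 CPM was 0.992. The column headed logConc was therefore turned around before use. All coordinates are dm3, as in the count tables. Current symbols and exonic lengths came from a later reference annotation through the NCBI gene number, which matched 14468 of 14770 genes. No coordinate was taken from that annotation.

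The totals of 34233132 to 69858688 counts per library set the precision: 3 counts, used as the floor, amount to 0.0429 to 0.0876 CPM. A chi-square comparison of counts per gene gave 87.5, 963 and 254 per gene for S2 replicates 1 and 2, S2 replicates 3 and 4 and the S2-AbdA libraries, so no library was a copy of another. Counts were analysed in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and further steps in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1.

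Genes were kept with filterByExpr on the 3 sets of libraries that the labels give, which left 9375. Libraries were scaled by the trimmed mean of M-values (TMM). The factors were 1.06, 1.06, 0.752 and 1.00 for S2 replicates 1 to 4 and 1.10 and 1.08 for S2-AbdA. The model was fitted to all 6 libraries with an indicator for S2 replicates 3 and 4, so that all sets shared 1 estimate of the spread while a difference between the S2 sets stayed out of the contrast. The contrast was S2-AbdA minus S2 replicates 1 and 2, tested by edgeR's quasi-likelihood F test with robust dispersion and a Benjamini-Hochberg adjusted p under 0.10. The common biological coefficient of variation was 0.291, with 3 residual and a median of 8.85 prior degrees of freedom. Standard errors were the log2 fold change over the square root of F. The design, the lists, the rule for named genes and the alternatives, apart from those said to be added, were fixed before the data were examined. CPM values are counts over the library's total count.

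On simulated data with the means and library sizes of these samples, for S2-AbdA against S2 replicates 1 and 2 and 9174 genes tested, the fit recovered 10 of 67 genes changed 2-fold (14.9%), 55 of 66 changed 4-fold (83.3%) and 60 of 64 changed 8-fold (93.8%). It called 15 unchanged genes (0.167%). A 2-fold change that is not past the test is therefore not shown to be absent. In the same simulation camera called the raised list (adjusted p = 3.36e-11) and 0 of 20 lists of unchanged genes. The simulated genes were drawn independently of each other, so this check does not bear on lists whose members vary together.

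The 35 gene lists (Hox genes, pathways, blood-cell and tissue markers, stress and housekeeping sets) were written before the data were examined, and 33 with at least 5 tested members were tested with limma's camera, with a preset inter-gene correlation of 0.01 and again with an estimated one, and with fry. The estimated correlation and fry were used in the main comparison only, so list values in the alternatives rest on the preset correlation. P-values were adjusted over the lists. Named genes were abd-A, the tested members of the Hox list, the 10 largest rises and 10 largest falls among genes past the test with a log2 fold change of at least 1 in size, at least 5 CPM in every library of the higher group and no overlap of S2-AbdA with any S2 library, and up to 4 members of smallest adjusted p from each list, or the 1 of smallest p in a list with none past the test. Other genes, such as gcm, rst and members of runs of neighbours, were named after their values were seen. Adjacent tested genes were compared with 100000 shuffles of positions. Chromosome arms were compared by two-sided Fisher's exact tests and, for medians, by 20000 permutations.

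Alternatives comprised other scalings, no filter or a filter of 5 CPM in 2 libraries, DESeq2, edgeR's likelihood ratio and exact tests, limma-voom, a test against a log2 fold change of 1, a threshold of 0.05, other sets of S2 libraries, a replicate block, and leaving out each library in turn. The replicate numbers were not used to pair libraries in the design. Leaving out a library of S2-AbdA or of an S2 set leaves that set with 1 library, which is then assumed to vary like the others. Other splits of the libraries into groups were not counted, since S2-AbdA has 2 libraries.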

Results

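Polyadenylated RNA was sequenced from Drosophila S2-DRSC cells, a line established from late embryos whose cells resemble blood cells, and from S2-DRSC cells that stably carried a transgene for HA-tagged AbdA. AbdA is the Hox transcription factor that patterns the abdomen. All cells had been kept in 10 µM copper sulphate for 24 h. There were 4 libraries of S2 cells (S2) and 2 libraries of the transfected cells (S2-AbdA). The S2 libraries held 34233132, 43763397, 54021037 and 69858688 counts in replicates 1 to 4, and the S2-AbdA libraries 47418230 and 46346075. Of the 14770 genes in the count tables, 9375 had enough counts to be tested. The question was which genes differ in expression between cells without and cells with the AbdA transgene. The labels name no cells transfected without AbdA, so effects of AbdA cannot be told apart from those of the stable transfection. The labels tie the authors' comparison to replicates 1 and 2 of both groups, so each fold change was S2-AbdA over S2 replicates 1 and 2, and the value against S2 replicates 3 and 4 was kept beside it. A gene rose or fell where its Benjamini-Hochberg adjusted p from edgeR's quasi-likelihood test lay under 0.10. Nothing in the labels says that replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical. Levels are given in CPM, counts per 1e+06 counts of the library, as mean ± SD with n = 2 per set, unless single libraries are named.

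The transfected gene, abd-A (gene number 42037, dm3 chromosome 3R, 12632936 to 12655474), was at 14099 ± 4511 CPM in S2-AbdA (SD, n = 2). Its counts were 819828 and 505607 in the S2-AbdA libraries, or 1.73% and 1.09% of all counts. S2 replicates 1 and 2 held 996 and 2308 counts (29.1 and 52.7 CPM), whereas S2 replicate 3 held 0 and S2 replicate 4 held 3. The log2 fold change over S2 replicates 1 and 2 was 8.39 (SE 0.61, adjusted p = 5.92e-05). Over the 3 counts that S2 replicates 3 and 4 held in all, the ratio was 583714, with a 95% counting interval of 199736 to 2.83e+06. Such intervals and floors cover counting error only. The other Hox genes, lab, pb, Dfd, Scr, Antp, Ubx and Abd-B, had no more than 6 counts in any library, and so did hth and ftz. Among the cofactors, exd, the partner of Hox proteins on DNA, had a log2 fold change of 0.35 (SE 0.35, adjusted p = 0.823). The trunk gene tsh and its paralogue tio had values of 1.19 (adjusted p = 0.124) and 0.95 (adjusted p = 0.312), which did not pass the test, while against S2 replicates 3 and 4 both were higher in S2-AbdA (2.96 and 2.07, adjusted p = 0.00116 and 0.0129). Of the 4 tested members of the list of Hox genes and cofactors, abd-A alone rose, and 3 rose adjusted over the list alone. The abd-A call was lost only where all 4 S2 libraries were taken as 1 group (log2 fold change 9.39, adjusted p = 0.267).

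**Figure D1:**
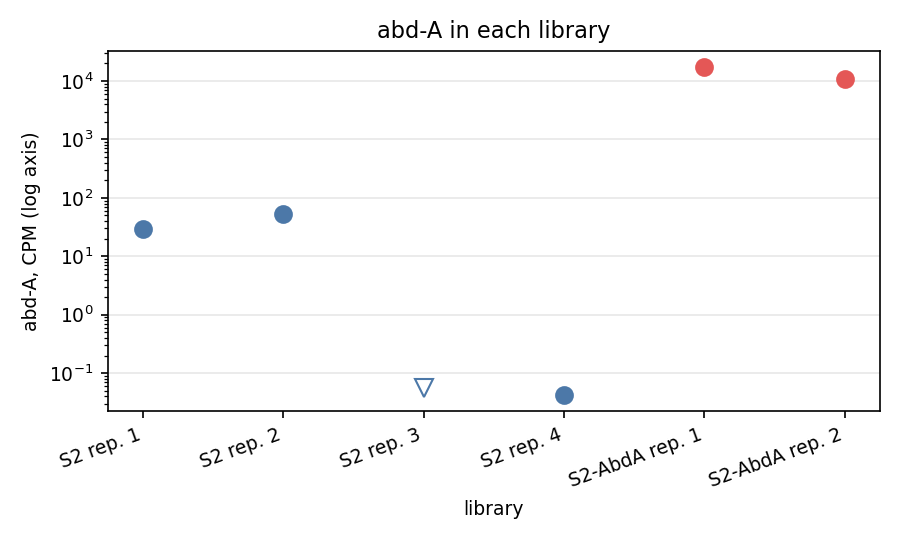
CPM of abd-A in each of the 6 libraries, on a log axis. The open triangle stands for S2 replicate 3, drawn at its floor of 3 counts because it held 0, and the S2-AbdA libraries lie at 17289 and 10909 CPM.

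The S2 libraries differed among themselves along the same label. Heat shock genes were lower in S2 replicates 3 and 4 than in replicates 1 and 2, with a median log2 difference of -3.33 over 13 members, 12 of which passed the test. Of the 17 tested plasmatocyte genes, markers of a blood cell, 10 were lower in replicates 3 and 4, 0 were higher and 7 did not pass the test, with a median of -1.92 over the list. The scavenger receptor gene Sr-CI stood at 35.6 ± 19.1 CPM in replicates 1 and 2 and at 0.25 ± 0.0909 in replicates 3 and 4 (log2 difference -6.85, adjusted p = 1.08e-04). Genes of mitochondrial ribosomal proteins were higher in replicates 3 and 4, by a median of 1.25 over 72 members, with 66 past the test. Differences between the S2 sets followed exonic length (Spearman's rho -0.341 across genes), and the median exonic length of these genes was 783 bases. After a correction on length, added after the data were seen, their median was 1.02 with 67 past the test, that of plasmatocyte genes -1.34 with 8 lower, and that of heat shock genes -3.63 with 10 lower and 1 higher. In all, 3470 genes differed between these sets, 1698 higher and 1772 lower in replicates 3 and 4. Without trimmed-mean scaling, on library size alone, the split was 760 higher and 1738 lower (30.4% higher in place of 48.9%) with the median of all genes at -0.27, and with upper quartile scaling it was 1170 and 1981 (37.1%) with the median at -0.15. The number of genes was 1652 without S2 replicate 1, 1048 without S2 replicate 2 and 6354 without S2 replicate 4. Across genes, Pearson's r of log2(CPM + 1) was 0.996 between S2 replicates 1 and 2, 0.982 between S2 replicates 3 and 4, 0.994 between the S2-AbdA libraries and 0.946 to 0.977 between the S2 sets. Genes are not independent replicates. The reason for the labels' distinction is not given in the sources used here.

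Against S2 replicates 1 and 2, 971 genes changed in S2-AbdA. Cht2, which encodes a chitinase, and if, which encodes the integrin subunit αPS2, rose, and Cyp12a4, a mitochondrial cytochrome P450, and mab-21 fell. In all, 281 genes rose and 690 fell, each by at least 2-fold, and 1598 genes had an unadjusted p under 0.05. Against S2 replicates 3 and 4, 1377 genes rose and 1600 fell. On library size alone that split was 1536 and 779 (66.3% higher in place of 46.3%), with the median of all genes at 0.30.

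Of the 281 genes that rose, 204 (72.6%) also rose against S2 replicates 3 and 4, and 8 fell. Of the 690 that fell, 176 (25.5%) also fell against S2 replicates 3 and 4, and 143 rose. Independent lists of these sizes would share 41.3 rises and 118 falls. Of the genes that fell, 522 (75.7%) were also lower in S2 replicates 3 and 4 than in S2 replicates 1 and 2. Those comparisons share S2 replicates 1 and 2, which were not split between them, so part of this number may come from sharing them. Independent lists would share 130 falls and 50.9 rises, where 65 rises were shared. In 20 simulations of unchanged groups at most 1 gene fell in both and none rose in both. Those simulations gave all libraries the same means and called at most 4 genes against S2 replicates 1 and 2. They therefore cannot show how many of the shared calls come from sharing libraries. The correlation across genes was 0.499, no higher than the simulated mean of 0.510 from the shared libraries alone, and the covariance was 0.781 against 0.114. The comparisons with the separate S2 sets share the S2-AbdA libraries. In their 20 simulations of unchanged groups, limited in the same way, no gene rose in both and at most 1 fell in both. The correlation across genes of the log2 fold changes was 0.267, against a simulated mean of 0.497 from the shared libraries alone, and the covariance was 0.375 against 0.110, a difference of 0.265. The S2-AbdA libraries were not split between the comparisons, so part of the excess may come from sharing them. Leaving out S2 replicate 3 or 4 leaves the other alone in its set, so neither then adds to the estimate of the spread. A fit of only replicates 1 and 2 of both groups, where the same holds, gave 1744 changed genes. The number of rises fell to 131 without S2 replicate 1, 164 without S2 replicate 2 and 179 without S2-AbdA replicate 1.

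**Figure D2:**
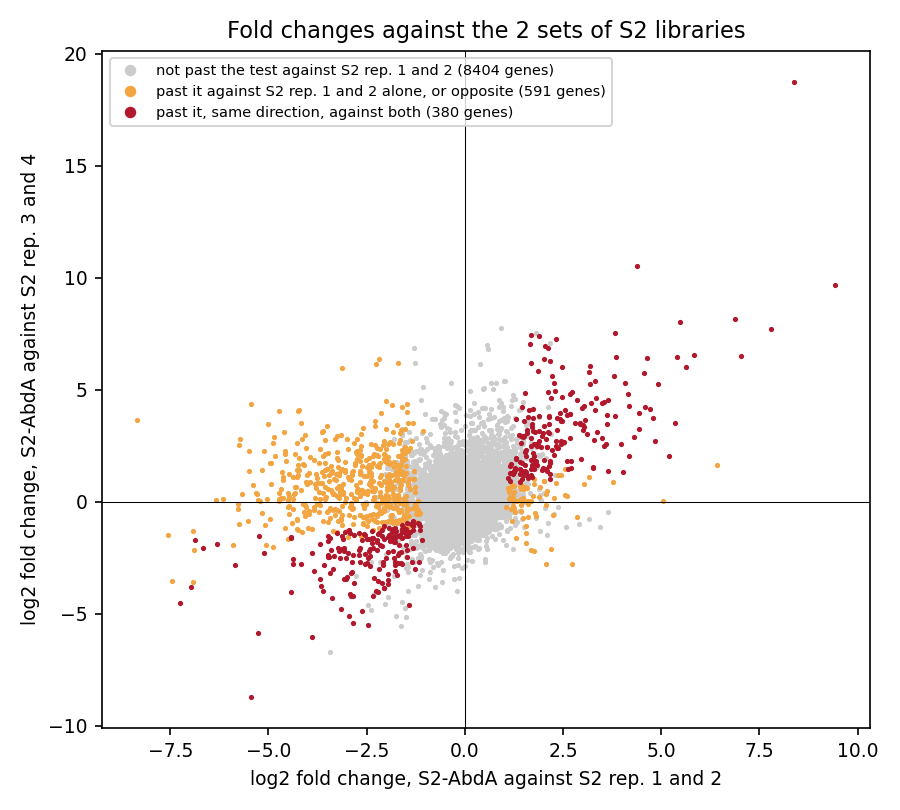
Each point is a tested gene, with its log2 fold change in S2-AbdA over S2 replicates 1 and 2 on the x axis and over S2 replicates 3 and 4 on the y axis. The 380 genes past the test in the same direction against both sets are set apart from the 591 past it against replicates 1 and 2 alone or in the opposite direction, and from the 8404 not past it.

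The largest rises were chosen among genes of at least 5 CPM in both S2-AbdA libraries, with both of these above all 4 S2 libraries. They included Cht2, the integrin gene if and the protease gene CG6361, beside genes of unknown function. CG15046 (gene number 32833, X, 18381681 to 18383519) went from 0.231 ± 0.00368 to 164 ± 0.696 CPM (log2 fold change 9.42, SE 0.54, adjusted p = 4.86e-06). CG31148, now Gba1a (42796, 3R, 19526343 to 19528327), rose from 0.0749 to 17.9 CPM (7.79, SE 0.64). CG15044 (32834, X, 18385216 to 18386029), next to CG15046, rose by 6.87 (SE 0.52). Cht2 (38223, 3L, 1752391 to 1755668) rose from 1.41 ± 0.116 to 61.5 ± 1.49 CPM (5.41, SE 0.48), and its neighbour CG13921 (38222, 3L, 1746907 to 1752327) rose by 4.56 (SE 0.45). CG34034 (3885584, 3R, 17564067 to 17564832) rose from 5.69 to 238 CPM (5.34, SE 0.59). The integrin gene if (32661, X, 16646222 to 16677467) rose from 2.09 ± 0.344 to 56.7 ± 4.69 CPM (4.72, SE 0.44). CG6361, now Hayan (32831, X, 18374016 to 18377805), a clip-domain serine protease of the melanization cascade, rose by 4.43 (SE 0.48). A level above S2 replicates 3 and 4 was part of the choice, and besides abd-A the values of the largest rises against that set were 2.73 (kirre) to 9.66 (CG15046).

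The gene kirre (31292, X, 2634417 to 3026824), which encodes a cell adhesion protein of myoblast fusion, rose from 2.70 ± 0.0224 to 80.5 ± 58.8 CPM (4.85, SE 0.57, adjusted p = 4.55e-04) and by 2.73 against S2 replicates 3 and 4. Its annotated span contains other genes, w among them, and the strand setting of the counting is not given in the sources used here, so its value is uncertain.

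The largest falls, chosen by the same rule with at least 5 CPM in S2 replicates 1 and 2 and both S2-AbdA libraries below all 4 S2 libraries, included Cyp12a4, a cytochrome P450 gene, and mab-21. CG13559 (37720, 2R, 19390469 to 19391338) fell from 6.88 to 0.0537 CPM (log2 fold change -6.97, SE 0.85), and CG10205 (36650, 2R, 10720338 to 10721456) from 10.0 ± 0.335 to 0.0853 ± 0.00134 CPM (-6.87, SE 0.59). CG10479 (38674, 3L, 5960645 to 5969107) fell from 29.8 to 0.525 CPM (-5.86, SE 0.54). Cyp12a4 (42294, 3R, 14960880 to 14962858) fell from 159 ± 22.9 to 7.54 ± 0.439 CPM (-4.43, SE 0.46, adjusted p = 2.55e-04). CG17597 (35140, 2L, 18829060 to 18830653), CG34323 (5740207, X, 11964470 to 11965296), CG13358 (31029, X, 697504 to 701337), CG7408 (39991, 3L, 17872196 to 17876748) and CG6018, now gas (37572, 2R, 18437599 to 18439618), had values of -4.42, -4.41, -3.89, -3.70 and -3.65. CG34323, CG13358 and CG6018 overlap annotated neighbours, so their counts are uncertain in the same way.

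The gene mab-21 (44127, X, 5902216 to 5907211), a conserved developmental gene, stood at 220 ± 47.7 CPM in S2 replicates 1 and 2, at 229 ± 3.08 in replicates 3 and 4 and at 18.3 ± 3.14 in S2-AbdA (-3.62, SE 0.40, and -3.99 against replicates 3 and 4). Lower levels than in S2 replicates 3 and 4 were part of the choice of the 10 largest falls, so their values against that set are no separate result, and of all 690 falls 176 fell against both sets. The smallest of those values were -1.57 for CG17597 (adjusted p = 0.0764), -1.62 for Cyp12a4 and -1.70 for CG10205 (adjusted p = 0.0748). Each of these 20 genes, abd-A included, kept its call with any 1 of the 6 libraries left out.

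**Figure D3:**
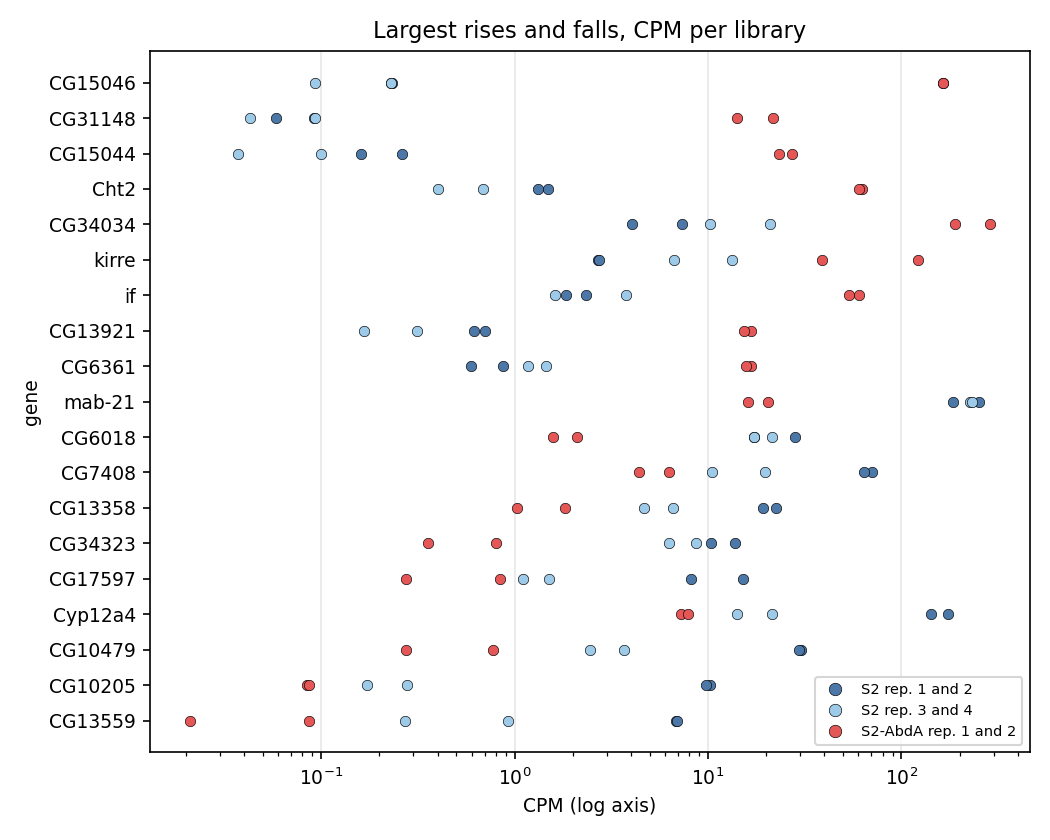
CPM, on a log axis, in each of the 6 libraries for the 9 largest rises besides abd-A and the 10 largest falls. The genes were chosen so that both S2-AbdA libraries lie outside the range of the 4 S2 libraries.

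Of the 17 tested genes of the plasmatocyte, the phagocytic blood cell, 8 fell in S2-AbdA against S2 replicates 1 and 2, 1 rose and 8 did not pass the test, with 9 falls and 1 rise adjusted over the list alone. The scavenger receptor gene Sr-CI fell from 35.6 ± 19.1 to 1.53 ± 1.07 CPM (log2 fold change -4.56, SE 0.63), and the phagocytosis receptor gene eater from 75.5 ± 13.3 to 5.95 ± 5.16 CPM (-3.69, SE 0.62). The Nimrod genes nimC1 and nimB4 had log2 fold changes of -3.30 and -4.16. The member that rose was gcm, a regulator of glial and blood-cell fate, at 0.359 and 7.77 CPM in the S2-AbdA libraries, and its call was lost with any library but S2-AbdA replicate 1 left out. In S2 replicates 3 and 4, Sr-CI stood at 0.25 and eater at 0.909 CPM and nimC1 held 3 counts in all. Against that set 6 members of the list were higher and 1 lower in S2-AbdA, and camera turned upwards (adjusted p = 0.0474). Camera with a preset correlation of 0.01 placed the list below other genes (adjusted p = 8.87e-06), and with an estimated correlation the adjusted p was 0.706. Without S2 replicate 3 the calls of eater (adjusted p = 0.144) and nimB4 (adjusted p = 0.120) were lost.

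Immune recognition genes had 10 falls, 1 rise and 15 not past the test among 26 members, or 12 falls and 2 rises adjusted over the list alone. The peptidoglycan receptor gene PGRP-LE fell from 14.0 ± 2.30 to 2.81 ± 1.15 CPM (-2.35, SE 0.44) and Tep1, a complement-like gene, fell by 3.69 on the log2 scale. The Nimrod gene nimC4, an engulfment receptor gene that overlaps an acetylcholine receptor gene, rose from 4.95 ± 0.348 to 69.0 ± 0.815 CPM (3.76, SE 0.57). Against S2 replicates 3 and 4, PGRP-LE was higher in S2-AbdA (1.75), Tep1 did not differ past the test (0.12) and nimC4 did not pass it (0.89), and 8 members were higher and 3 lower, with camera upwards (adjusted p = 0.0424). Without S2-AbdA replicate 1, 4 members fell, and without S2 replicate 2, 6. The list's adjusted p was 0.00739 with the preset correlation, 0.843 with an estimated correlation and 0.268 without S2-AbdA replicate 1. The crystal cell list had 4 tested members, too few for camera, and 3 of them fell, with 3 falls adjusted over the list alone: the prophenoloxidase genes proPO-A1 (-5.76) and proPO45 (-4.14) and the Runx gene lz (-3.15). The counts of proPO-A1 came mostly from S2 replicate 1 (84.7 CPM, against 14.1 in replicate 2). The call of proPO-A1 was lost without S2 replicate 3 or 4 (adjusted p = 0.192 and 0.142), that of lz without S2 replicate 1 (adjusted p = 0.115), and that of proPO45 without S2 replicate 1, 3 or 4 (adjusted p = 0.905, 0.341 and 0.257). The values against S2 replicates 3 and 4, -0.98 for proPO-A1, -1.35 for proPO45 and 1.39 for lz, were not past the test. Of 5 lamellocyte genes 2 fell, 2 adjusted over the list alone, the integrin genes betaInt-nu (-2.48) and alphaPS4 (-1.53). Against S2 replicates 3 and 4 betaInt-nu was higher in S2-AbdA (1.16, adjusted p = 0.0768) and alphaPS4 was not past the test (0.22). The call of alphaPS4 was lost without S2 replicate 2 or either S2-AbdA library (adjusted p = 0.585, 0.166 and 0.263). In the antimicrobial peptide list none of 13 members passed the test, but 4 fell without S2 replicate 3, 3 without S2 replicate 4 and 2 without S2-AbdA replicate 2, 1 rose without S2 replicate 1, and 2 rose and 6 fell against S2 replicates 3 and 4.

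Adhesion and matrix genes moved in both directions against S2 replicates 1 and 2. Among 23 cell adhesion genes 3 rose, if, kirre and rst, and 5 fell, with 4 rises and 8 falls adjusted over the list alone. In S2-AbdA 9 were higher and 1 lower than in S2 replicates 3 and 4, with a median of 1.02, and 13 of the 23 were lower in that set than in S2 replicates 1 and 2. Ten-a, a teneurin, fell from 39.8 ± 1.30 to 4.82 ± 1.39 CPM (-3.09, SE 0.47, and -2.21 against S2 replicates 3 and 4). The leucine-rich repeat gene caps fell from 54.5 ± 14.1 to 6.92 ± 0.175 CPM (-3.02), and stood at 5.02 in S2 replicates 3 and 4. Among 21 extracellular matrix genes 2 rose and 2 fell, with 3 and 5 adjusted over the list alone, and 5 were higher and 2 lower than in S2 replicates 3 and 4. Timp, the inhibitor of matrix metalloproteinases, rose from 0.893 ± 0.10 to 16.3 ± 0.158 CPM (4.15, SE 0.49), and the collagen gene mp from 2.83 ± 0.163 to 26.4 ± 9.20 CPM (3.18, SE 0.41). Both also rose against S2 replicates 3 and 4 (4.80 and 6.06). Timp lies within the span of Syn. The nidogen gene Ndg fell by 2.98 on the log2 scale but was higher than in S2 replicates 3 and 4 (2.36). The other matrix gene that fell, Pxn, is also in the plasmatocyte list and fell against both sets of S2 libraries. With 1 library left out its log2 fold change over S2 replicates 1 and 2 was -4.04 to -1.89, and its call was lost without S2 replicate 3 or 4. Of 18 axon guidance genes 1 rose and 4 fell, with the same numbers adjusted over the list alone, and 5 were higher and 3 lower than in S2 replicates 3 and 4. The Slit receptor gene lea, now robo2, fell from 66.2 ± 15.5 to 14.4 ± 0.884 CPM (-2.24, SE 0.37, and -2.17 against S2 replicates 3 and 4), and its ligand gene sli from 246 ± 32.3 to 42.9 ± 5.84 CPM (-2.56, SE 0.46), which was close to the 43.7 ± 33.0 CPM of S2 replicates 3 and 4.

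Signalling genes changed in small numbers. In the EGFR and FGF list 3 of 17 members rose and 2 fell, with 4 and 2 adjusted over the list alone. The secreted EGFR inhibitor gene aos rose from 197 and 268 CPM in S2 replicates 1 and 2 to 1068 ± 90.8 CPM (2.16, SE 0.41), the neuregulin-like ligand gene vn from 14.0 ± 1.64 to 46.6 ± 1.82 CPM (1.69, SE 0.34) and the FGF receptor gene htl from 101 ± 11.8 to 340 ± 11.9 CPM (1.71, SE 0.44). These 3 genes also rose against S2 replicates 3 and 4 (1.02, 2.47 and 1.62). The calls of vn (adjusted p = 0.172) and htl (adjusted p = 0.200) were lost without S2 replicate 1, and that of htl also without S2 replicate 2 (adjusted p = 0.116). Egfr itself fell from 0.839 to 0.0959 CPM, but it stood at 0.088 CPM in S2 replicates 3 and 4 and was not past the test against them (-0.21, adjusted p = 0.853). Its annotated span overlaps other genes, so its counts are uncertain. In the Notch list 1 of 12 rose, 1 adjusted over the list alone: fng, which encodes a glycosyltransferase that modifies Notch, at 1.66 and at 7.04 against S2 replicates 3 and 4. The call of fng was lost without S2 replicate 1, S2 replicate 2 or S2-AbdA replicate 2 (adjusted p = 0.148, 0.207 and 0.292). In the Wnt list 1 of 16 rose, 1 adjusted over the list alone. This was Wnt4, whose counts came from S2-AbdA replicate 2 (13.3 CPM) far more than from replicate 1 (0.527 CPM). Without S2-AbdA replicate 2 the log2 fold change of Wnt4 was 0.11 and its adjusted p 0.996, and its call was also lost without each of the S2 libraries (adjusted p = 0.394 to 0.772). The Wnt list had adjusted p = 0.0374 in camera with the preset correlation, 0.706 with an estimated correlation and 0.174 without S2 replicate 2.

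In the JAK/STAT list 2 of 10 fell, 2 adjusted over the list alone, both stress-induced Turandot genes. TotM fell from 28.2 ± 2.47 to 0.364 ± 0.217 CPM (-6.30, SE 0.79) and TotA by 3.77 on the log2 scale. TotA stood at 8.44 and 1.90 CPM in S2 replicates 1 and 2, and with 1 library left out its log2 fold change was -4.46 to -2.34. TotM was also lower than in S2 replicates 3 and 4 (-1.87, adjusted p = 0.0831), and TotA was not past the test against them (0.84). The list's adjusted p was 0.0290, and 0.706 with an estimated correlation. That estimate was -0.0202, so the higher value does not come from members varying together. The list turned upwards against S2 replicates 3 and 4 (adjusted p = 0.0407), with 5 members higher and 2 lower. Of 9 Hedgehog genes 2 fell, 2 adjusted over the list alone: boi (-1.98) and ci (-1.91). The value of boi was not past the test against S2 replicates 3 and 4 (0.66), where ci was higher in S2-AbdA (1.70, adjusted p = 0.0453), and the call of ci was lost without S2 replicate 2 or S2-AbdA replicate 1 (adjusted p = 0.275 and 0.220). Of 16 Dpp genes 1 rose, sog (1.27), with 0 adjusted over the list alone. Its call was lost without S2 replicate 1, S2 replicate 2 or either S2-AbdA library (adjusted p = 0.166 to 0.509) and against S2 replicates 3 and 4 (-0.47). Of 18 ecdysone response genes 2 fell, Eip71CD (-1.67) and Hr4 (-1.56), 2 adjusted over the list alone. Both calls were lost without S2 replicate 1 or S2-AbdA replicate 1 (adjusted p = 0.231 and 0.130 for Eip71CD, 0.528 and 0.543 for Hr4), and that of Hr4 also without S2 replicate 2 or S2-AbdA replicate 2 (0.121 and 0.143) and against S2 replicates 3 and 4 (-0.10), where Eip71CD also fell (-1.93). Of 13 published Hox targets 3 fell, and 6 fell adjusted over the list alone. The homeobox gene bap held 817 counts in S2 replicates 1 and 2 and 3 in S2-AbdA, a ratio of 327 with a 95% counting interval of 112 to 1591, and it held no count in S2 replicates 3 and 4. The pro-apoptotic gene rpr fell from 25.2 ± 5.23 to 4.81 ± 0.741 CPM (-2.43) and stood at 1.18 in S2 replicates 3 and 4. The Hox target list had adjusted p = 0.0374, 0.706 with an estimated correlation and 0.116 without S2-AbdA replicate 1. It turned upwards against S2 replicates 3 and 4 (adjusted p = 0.0680), with 5 members higher and 1 lower. Of 14 apoptosis genes 3 fell, rpr, W (-1.69) and Corp (-2.21), and 3 fell and 1 rose adjusted over the list alone. The call of W was lost without S2 replicate 1, S2 replicate 2 or either S2-AbdA library (adjusted p = 0.118 to 0.307) and that of Corp without S2 replicate 1 or S2-AbdA replicate 2 (0.393 and 0.183). Against S2 replicates 3 and 4, 0 apoptosis genes fell in edgeR's test and 3 rose, rpr among them (1.64, adjusted p = 0.0344), while W (0.92) and Corp (-0.53) were not past it.

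Of 12 metal response genes 4 rose, with 4 adjusted over the list alone: the zinc transporter gene ZnT35C and the metallothionein genes MtnB, MtnD and MtnE. MtnD went from 10.6 ± 7.50 to 51.6 ± 19.0 CPM (2.24, SE 0.54), and stood at 60.4 ± 14.5 CPM in S2 replicates 3 and 4. ZnT35C went from 0.337 ± 0.105 to 2.32 ± 0.355 CPM (2.72, SE 0.46), below the 12.6 ± 0.865 CPM of S2 replicates 3 and 4. MtnA and ZnT35C were lower in S2-AbdA than in that set, and MtnB (0.19), MtnD (-0.60) and MtnE (-0.13) were not past the test against it. The list's adjusted p was 0.00739, and 0.843 with an estimated correlation, and against S2 replicates 3 and 4 it turned downwards (adjusted p = 0.511). The calls of MtnD and MtnE were lost without S2 replicate 1, 3 or 4 (adjusted p = 0.183, 0.149 and 0.111 for MtnD, and 0.253, 0.159 and 0.119 for MtnE), and that of MtnB without S2 replicate 1 (0.383) or S2-AbdA replicate 1 (0.195).

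No heat shock gene of 13 passed edgeR's test (1 with an unadjusted p under 0.05, and 1 each with DESeq2 and the likelihood ratio test, 2 with the exact test and 0 with limma-voom). With 1 library left out, 4 rose without S2 replicate 2 or S2-AbdA replicate 2, 2 without S2 replicate 3 or 4, and 0 without S2 replicate 1 or S2-AbdA replicate 1. Against S2 replicates 3 and 4, 11 of them were higher in S2-AbdA, and the copies of Hsp70 among them cannot be told apart where reads were shared. Camera gave the list adjusted p = 0.0374 upwards, 0.865 with an estimated correlation, 0.638 without S2 replicate 1 and 0.268 without S2-AbdA replicate 1. Of 23 detoxification genes 1 rose, GstD5, with 0 adjusted over the list alone, and its call was lost without S2 replicate 1 (adjusted p = 0.365) or S2-AbdA replicate 1 (adjusted p = 0.339).

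Among tissue lists, 2 of 9 ovarian and germline genes fell, and 6 fell adjusted over the list alone. The piRNA gene aub fell from 50.3 ± 2.65 to 6.64 ± 2.11 CPM (-2.96, SE 0.44), with 2.56 CPM in S2 replicates 3 and 4. The other fall was bam (-2.11, and -1.53 against S2 replicates 3 and 4), whose call was lost without S2 replicate 1 or S2-AbdA replicate 1 (adjusted p = 0.128 and 0.216). The list's adjusted p was 0.00191, 0.706 with an estimated correlation and 0.412, upwards, against S2 replicates 3 and 4. Its estimated correlation was -0.0857, below the preset 0.01, so the 0.706 does not come from members varying together. This list was also the only one past fry's directional test (adjusted p = 0.0485). Of 14 muscle genes 1 fell, Mlc2 (38.6 ± 11.8 to 2.77 ± 0.0146 CPM, with 2.52 in S2 replicates 3 and 4), and 1 adjusted over the list alone. Of 14 neural genes 1 rose and 2 fell, with 2 and 3 adjusted over the list alone. The synaptic gene Snap25 rose from 0.130 to 1.68 CPM (3.64, and 4.54 against S2 replicates 3 and 4). The falls were Appl (-2.44) and Syt1 (-2.71), not past the test against S2 replicates 3 and 4 (0.80 and 0.46), and the call of Syt1 was lost without S2 replicate 2 or either S2-AbdA library (adjusted p = 0.125 to 0.251). Of 6 fat body genes 1 fell, Rfabg, and 3 adjusted over the list alone, and the call of Rfabg was lost without S2 replicate 2 (adjusted p = 0.168). Of 9 dosage compensation genes 1 fell, the RNA roX1, and 1 adjusted over the list alone, and this call was lost without S2 replicate 2 (adjusted p = 0.134) and against S2 replicates 3 and 4 (-0.69, adjusted p = 0.384). Of 20 autophagy genes 1 fell, Mitf (-1.14, and -1.28 against S2 replicates 3 and 4), and 0 adjusted over the list alone. The call of Mitf was lost without S2 replicate 1, S2 replicate 2 or either S2-AbdA library (adjusted p = 0.355 to 0.509).

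Few growth and housekeeping genes passed the test against S2 replicates 1 and 2. Of 88 ribosomal protein genes 2 fell, RpS10a (-3.33, and -2.42 against S2 replicates 3 and 4) and RpS5b (-2.58, not past the test against them, adjusted p = 0.163), which are low-level paralogues, with 2 adjusted over the list alone. The ribosomal list had adjusted p = 0.0810 downwards, 0.981 with an estimated correlation, and 0.205, 0.212, 0.148 and 0.486 without S2 replicate 1, S2 replicate 2, S2-AbdA replicate 1 and S2-AbdA replicate 2. No gene passed edgeR's test among 72 mitochondrial ribosomal, 30 cell cycle, 20 Polycomb and trithorax, 14 unfolded protein response, 13 glycolysis and 12 transcriptional pausing genes, and 0 in each of these lists had an unadjusted p under 0.05. DESeq2, the likelihood ratio test and limma-voom called 0 in each, and the exact test called 1, 1, 2, 1, 2 and 0. Without S2 replicate 3 or 4, 2 Polycomb and trithorax genes and 1 unfolded protein response gene fell and 1 glycolysis gene rose, and 1 mitochondrial ribosomal gene rose without S2 replicate 3. In the comparison with S2 replicates 3 and 4, 60 mitochondrial ribosomal, 37 ribosomal protein, 11 cell cycle, 3 unfolded protein response, 2 pausing, 1 Polycomb and trithorax and 1 glycolysis genes were lower in S2-AbdA, and 2 glycolysis, 2 unfolded protein response and 1 cell cycle genes were higher. Among 11 JNK pathway genes edgeR called 0 (1 with an unadjusted p under 0.05, and 1 each with DESeq2, the likelihood ratio test and the exact test, 0 with limma-voom), while 1 rose without S2 replicate 3 or 4 and 3 rose over S2 replicates 3 and 4. Of the 13 antimicrobial peptide genes 3 had an unadjusted p under 0.05, and the exact test called 4 while the other tools called 0. In these lists without calls 0 members passed adjusted over the list alone.

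Of the 33 lists tested with camera, 9 passed with the preset correlation, 0 with an estimated correlation, 15 against S2 replicates 3 and 4, and 5 without S2-AbdA replicate 1. No estimated correlation was used against S2 replicates 3 and 4, so the values of the lists against that set rest on the preset one. In the 26 lists with calls, 79 members passed edgeR's test, counting a gene once in each list that holds it. The number was 59 without S2 replicate 1 or S2 replicate 2, 58 without S2-AbdA replicate 1, 78 without S2-AbdA replicate 2, 129 without S2 replicate 3 and 122 without S2 replicate 4. It was larger by over 1.5 times in 18 lists without S2 replicate 3 and 16 without S2 replicate 4. It was smaller by over 1.5 times in 9 lists without S2 replicate 1, 10 without S2 replicate 2, 8 without S2-AbdA replicate 1 and 5 without S2-AbdA replicate 2, of which 5, 5, 4 and 3 had no member past the test. For lists whose numbers are not given above, those higher and lower against S2 replicates 3 and 4 were 5 and 1 for EGFR and FGF, 3 and 1 for Notch, 4 and 0 for Wnt, 2 and 0 each for Dpp and Hedgehog, 5 and 1 each for ecdysone and autophagy, 2 and 1 for muscle, 3 and 0 for neural, 3 and 1 for ovarian, 4 and 6 for detoxification, 1 and 1 for fat body, 1 and 0 for lamellocyte and 0 and 1 for dosage compensation genes. For some lists that did not pass, median, mean and test differed in sign. Axon guidance had a median log2 fold change of 0.05, a mean of -0.35 and a test downwards. Cell adhesion had 0.01 and -0.19 and the Hedgehog list 0.11 and -0.24, both downwards. Apoptosis had 0.21 and -0.19, neural genes 0.05 and -0.06, and pausing genes 0.03 and -0.01, each upwards. Muscle genes had -0.04 and -0.19 and mitochondrial ribosomal genes -0.03 and -0.06, with a test upwards.

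**Figure D4:**
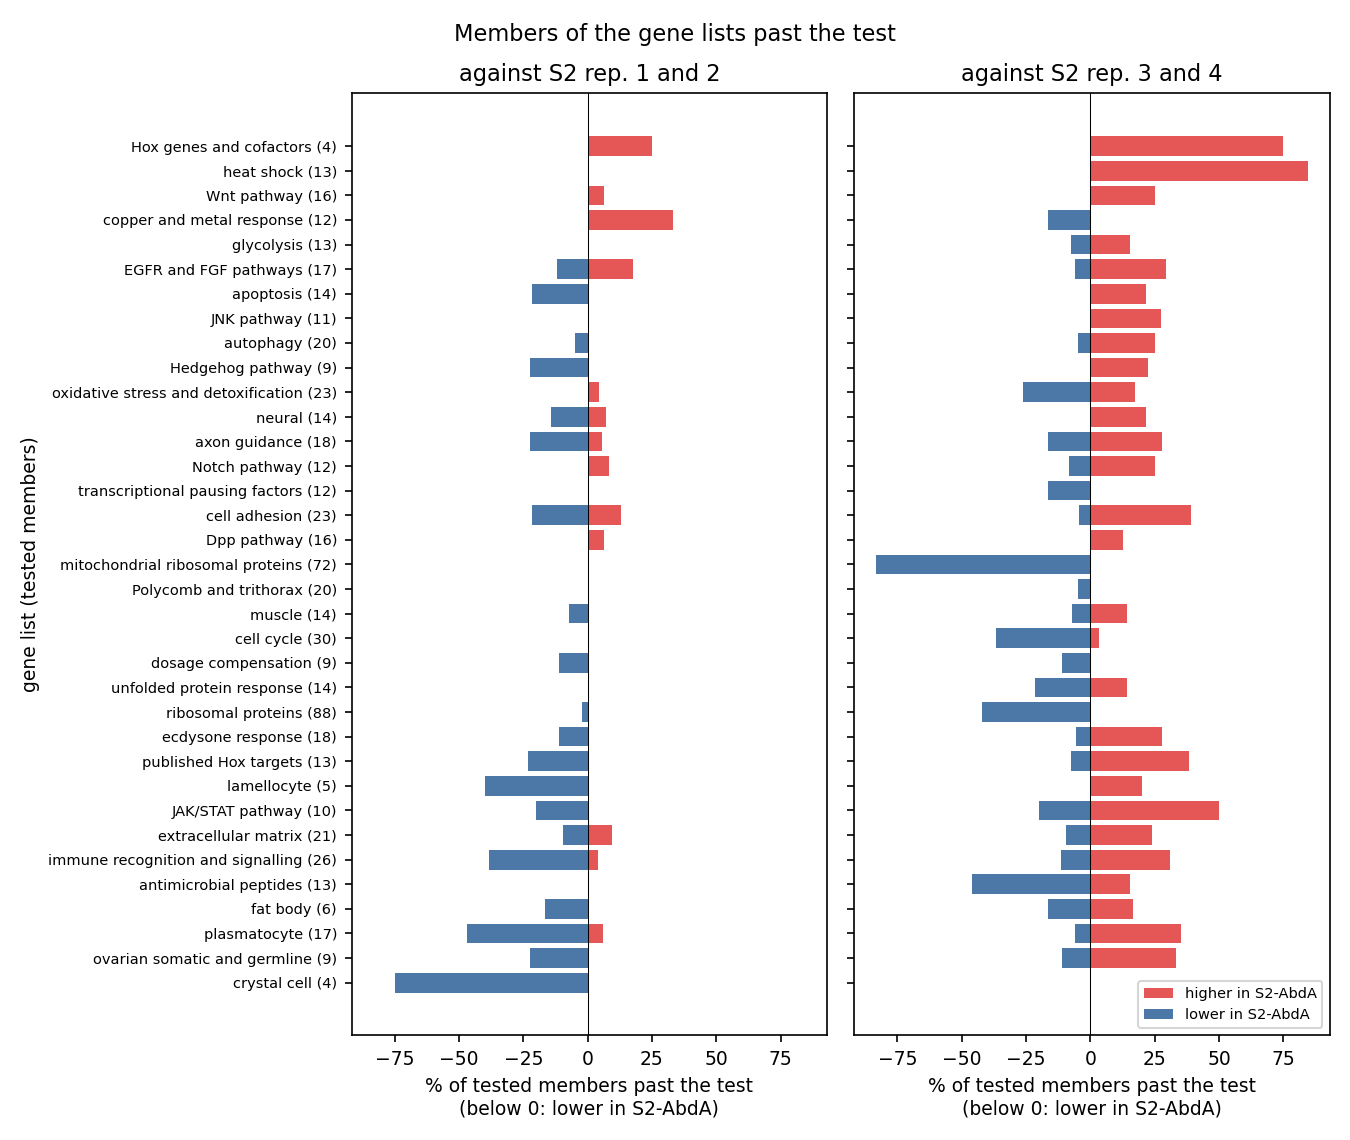
For each gene list, the percent of its tested members that rose or fell in S2-AbdA, against S2 replicates 1 and 2 in the left panel and against S2 replicates 3 and 4 in the right panel. Plasmatocyte genes have 8 falls and 1 rise among 17 on the left and 6 rises and 1 fall on the right, and mitochondrial ribosomal genes are at 0 on the left and at 60 falls of 72 on the right.

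The authors' deposited table lists 2122 genes, all with a false discovery rate under 0.10. In the authors' deposited table the column headed logConc follows the log2 ratio of S2 over S2-AbdA, and the column headed logFC follows the mean log2 level. With the former turned around, the authors' deposited table holds 895 genes higher and 1227 lower in S2-AbdA, abd-A among them at 8.37. Of the 971 genes changed here, 970 are in the authors' deposited table with the same direction, where independent lists would share 204. Of the 1973 genes in the authors' deposited table that were tested here, 1003 did not pass the test used here. The exact test on replicates 1 and 2 of both groups called 1897 genes, of which 1741 are in the authors' deposited table. The table and the counts come from the same libraries, so this overlap is not independent evidence.

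Genes that changed in the same direction often lay side by side. A run of 5 genes on X (18374016 to 18388197), CG6361, psh, CG15046, CG15044 and CG15043, rose by 2.38 to 9.42 on the log2 scale. CG6361 and psh encode serine proteases upstream of Toll and melanization. A run of 4 on 3R (17498025 to 17574725), CG31176, CG34034, CG5849 and CG31343, rose by 2.15 to 5.34. All members of both runs also rose against S2 replicates 3 and 4. The longest falling runs held 7 genes, and a run of 5 on 2L (13967464 to 13976753) held nimB3, nimB4, nimB5, He and nimC1, none of which also fell against S2 replicates 3 and 4. Of 9314 adjacent pairs of tested genes, 272 (2.92%) changed in the same direction, against a mean of 58.7 in 100000 shuffles of positions (one-sided permutation p = 1e-05, the smallest that the shuffles give). Both members rose in 52 pairs (mean of shuffles 7.73) and both fell in 220 (mean 51.0). With calls against S2 replicates 3 and 4, where more genes passed the test, 738 pairs changed in the same direction against a mean of 470 (permutation p = 1e-05), 348 rising (mean 197) and 390 falling (mean 273).

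By chromosome arm, rises were most frequent on X, where 66 of 1584 genes (4.17%) rose (two-sided Fisher's exact test, adjusted p = 0.00771 over 6 arms). On 2L 158 of 1688 genes (9.36%) fell (adjusted p = 0.00594) and 33 (1.95%) rose (adjusted p = 0.0302), and on 2R 41 of 1893 (2.17%) rose (adjusted p = 0.0752). With only genes of at least 5 CPM in 2 libraries the X share was 3.90% (adjusted p = 0.00112), while 2L had 6.28% falls (0.381) and 1.53% rises (0.141) and 2R 1.66% rises (0.145). The 77 genes of chromosome 4 had a median log2 fold change of -0.35 (permutation test, adjusted p = 3e-04). The same test gave adjusted p = 0.00825 for X (median 0.013), 0.0368 for 2R (0.0017) and 0.0872 for 3L (-0.042). All these arm tests treat genes as independent, while changed genes often lay side by side, so their p-values may be too small. The X excess lay in a segment near the centromere, from 19561266 to 22417005, where 28 of 129 genes rose (21.7%, against 2.74% of all other genes) and 7 fell. This segment was chosen after its values were seen. Without the segment 2.61% of X genes rose. Its genes had a median log2 fold change of 0.74, and 0.83 against S2 replicates 3 and 4, and 15 of its 28 rises also rose against that set.

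**Figure D5:**
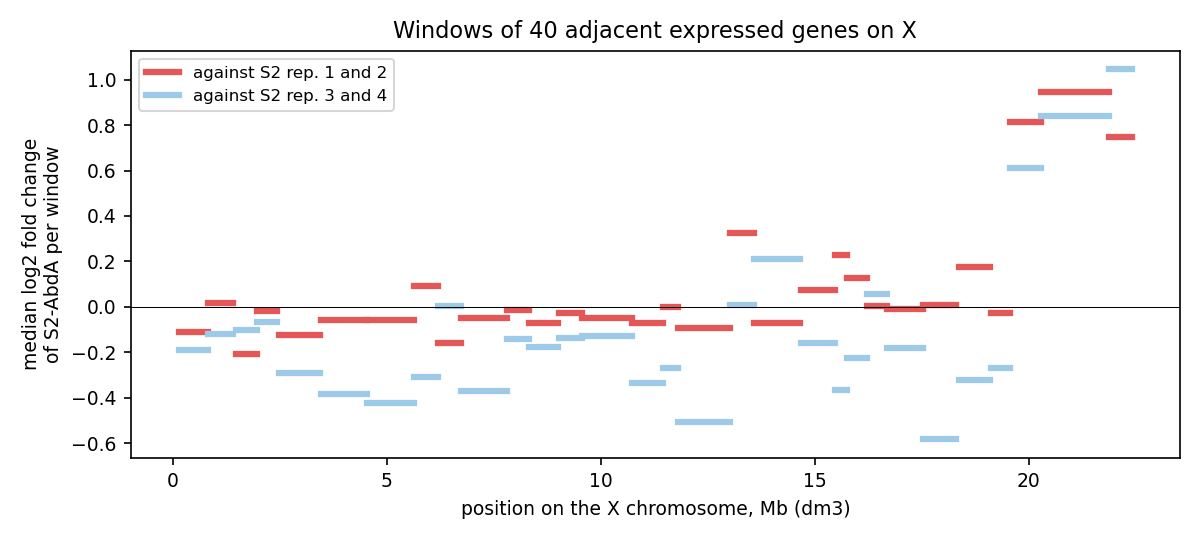
Median log2 fold change of S2-AbdA over S2 replicates 1 and 2, and over S2 replicates 3 and 4, in windows of 40 adjacent genes of at least 5 CPM along X in dm3 coordinates. Windows in the segment from 19561266 to 22417005 have the highest medians over S2 replicates 1 and 2, and no window elsewhere on the arms exceeds 0.43.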

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

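The correction on gene length, the test of S2 replicates 1 and 2 for an aberrant library, the tests of carry-over from S2-AbdA and of the proximal X segment, and the neighbour test outside that segment, were chosen only after the result was seen. Of 91 results checked for a single S2 library far from the other 3, 4 stood out, about what chance gives at 1 in 20. CG15046 was at 0.0926 CPM in S2 replicate 3, against 0.229 to 0.234 in the others. The EGFR inhibitor gene aos was at 642 CPM in S2 replicate 4, against 197 to 268. In S2 replicate 1 the prophenoloxidase gene proPO-A1 was at 84.7 CPM, against 0.816 to 14.1, and proPO45 at 3.56 CPM, against 0.143 to 0.296.

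The largest structure in the data was the split of the S2 libraries, 3470 genes between replicates 1 and 2 and replicates 3 and 4. A bias by gene length may add to it, since the log2 difference fell with exonic length (Spearman's rho -0.341 across genes, with medians of 0.72 in the shortest quartile of genes and -0.47 in the longest). As the whole cause it is argued against by a correction on length in each library, after which 87.9% of the calls stayed. In all 4907 genes then differed, against 3447 of the genes with a known length before it. For an aberrant library among S2 replicates 3 and 4, 2618 genes differed without replicate 3 and 6354 without replicate 4. A split thus remained without replicate 3. Without S2 replicate 1 the number was 1652 and without S2 replicate 2 it was 1048, fewer than 50% of 3470. Each of these fits leaves 1 library in a set and changes the estimate of the spread, so the numbers cannot decide for either set. Chi-square per gene was 963 between S2 replicates 3 and 4. Between replicate 4 and S2 replicates 1 and 2 it was lower, 494 and 684, and between replicate 3 and these it was 1420 and 1702. Pearson's r across genes was 0.996 between S2 replicates 1 and 2, 0.982 between replicates 3 and 4 and at most 0.977 between the sets. An aberrant library in either set therefore stays open. A difference in library preparation or in the stock of cells stays open and untested. No biological explanation was tested, because the design names none.

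S2 replicates 1 and 2 held abd-A at 0.206% and 0.374% of the S2-AbdA mean, and S2 replicates 3 and 4 at 3 counts in all. RNA or reads of the S2-AbdA libraries could account for this. Of genes at 10 CPM or more in S2-AbdA and under 1% of that in S2 replicates 3 and 4, 9 were found, for which such carry-over needs 91.4 counts in S2 replicates 1 and 2. They held 7549, but most of these genes are expressed by S2 replicates 1 and 2 far above that share, so the sum cannot separate carry-over from expression. The most informative member, CG15046, held 18 counts (upper 95% bound 28.4) where 31.3 were needed, but as 1 gene it excludes nothing, and carry-over and a low level of abd-A in these cells cannot be told apart.

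Neighbouring genes rose together in 52 pairs. Overlapping genes and same-strand tandem copies that share reads are argued against as the whole cause. After same-strand, overlapping and same-stem pairs were left out, 20 pairs remained, against a mean of 4.21 in shuffles (permutation p = 1e-05, the smallest the shuffles give). Genes with CG or CR symbols never counted as same-stem. Tandem copies of such genes on opposite strands therefore stayed in and are not excluded. For gain of DNA copies by 1 factor per region, 23.1% of the pairs differed by more than their combined error allows. That lies above 20%, the bound set beforehand against 1 factor. The 95% interval of 12.5% to 36.8%, which was not part of that bound, includes it, so such a gain stays open. For the proximal X segment the first test used its 36 genes under 5 CPM, whose median was 0.062 (95% interval -0.26 to 0.32), below what 1 factor needs, but 1.25 (0.22 to 1.65) against S2 replicates 3 and 4, where low genes elsewhere had 0.60. A second test, chosen after that result, redrew the segment from every other gene of at least 5 CPM and used those left out. The region had first been found with all of these genes, and the redrawn bounds were the same. The left-out genes are therefore no independent test. Their median was 0.91 (0.73 to 1.12, 38 of 46 above 0), and 0.64 (0.021 to 1.12) against S2 replicates 3 and 4. Genes of at least 5 CPM elsewhere had -0.0071 against S2 replicates 1 and 2 and -0.21 against S2 replicates 3 and 4. The segment's genes of at least 5 CPM thus lay above those elsewhere against both sets. Against S2 replicates 1 and 2 this follows in part from the choice of the segment, and against S2 replicates 3 and 4 the interval was wide. For genes under 5 CPM the medians differed between the sets of S2 libraries. As 1 factor is not settled for either kind of gene, it stays open. Outside the segment 42 pairs rose together against 6.29 in shuffles.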

How the results depend on the processing

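The comparisons with the genes called against both S2 sets, the length correction, the neighbour test against S2 replicates 3 and 4 and X without its proximal segment were added after the data were seen. The direction of abd-A was kept in all alternatives, and its call was lost only with all 4 S2 libraries as 1 group (9.39, adjusted p = 0.267, the adjusted p of abd-A in the other alternatives being 5.27e-81 to 0.00177). Of 1554 values of the 75 other named genes past the test, 1328 kept direction and call, 201 lost the call and 25 changed sign. Of 251 values of the 12 named genes not past the test, 196 kept side and direction, 49 passed the test (8 of 12 with the exact test, 7 and 6 without S2 replicates 3 and 4) and 6 changed sign without passing it. For bap no value against S2 replicates 3 and 4 is given, since both sets were at the floor.

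The count of 971 changed genes (281 rose, 690 fell) became 440 (118 and 322) with the filter of 5 CPM in 2 libraries, where 6957 genes were tested. It became 1897 (831 and 1066) with the exact test on 4 libraries, 1744 (758 rose) in a fit of only these 4 libraries, and 46 (34 and 12) with all 4 S2 libraries as 1 group. Against S2 replicates 3 and 4 it was 2977 (1377 and 1600), tested against a log2 fold change of 1 it was 532 (108 and 424), and with calls against both S2 sets it was 380 (204 and 176). The length correction gave 614 rises. Leaving out 1 library gave 658 to 1829 changed genes, 131 to 762 rises and 480 to 1067 falls. The cause of these shifts was not tested, except that fewer genes or stricter bounds were set by the alternatives themselves. With a replicate block on replicates 1 and 2 of both groups 1592 genes changed and 658 rose. The numbers do not pair the libraries: the deviations of the 2 pairs correlated with r = -0.00872 across genes.

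Between the S2 sets 3470 genes differed, 1614 with the filter of 5 CPM, 913 against a log2 fold change of 1 and 2108 at a threshold of 0.05. After the length correction the number was 4907. Leaving out 1 library gave 1048 to 6354. Of the lists, 9 passed camera, 0 with an estimated correlation, 15 against S2 replicates 3 and 4, and 5 to 9 with 1 library left out. List values in the alternatives all rest on the preset correlation of 0.01. In the main comparison the estimate for mitochondrial ribosomal genes was 0.819, far above it. Camera does not use the gene test, so DESeq2, the likelihood ratio and exact tests, limma-voom and the bound on the fold change gave no further list values. The overlap with the authors' deposited table was 970 genes, or 1741 with the exact test. Shares of rises on 2L (1.53%), falls on 2L (6.28%) and rises on 2R (1.66%) were not past the test with the filter of 5 CPM. Rises on X without its proximal segment (2.61%, with the main filter) were not past the test either.

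These log2 fold changes changed sign against S2 replicates 3 and 4: sog -0.47, boi 0.66, ci 1.70, TotA 0.84, rpr 1.64, W 0.92, caps 0.19, ZnT35C -2.78 (also -1.81 with all S2 as 1 group), MtnD -0.60, MtnE -0.13, lz 1.39, Ndg 2.36, Tep1 0.12, PGRP-LE 1.75, PGRP-LC 0.34, betaInt-nu 1.16, alphaPS4 0.22, Appl 0.80, Syt1 0.46, aub 1.01, Sr-CI 2.28, eater 2.36, nimC1 2.78 and nimB4 3.51. The fitted value of nimC1 rests on 3 counts in those 2 libraries, where the ratio was 8.81 (95% counting interval 2.61 to 46.3). Among lists past the test in either setting, the direction of the list test also changed against S2 replicates 3 and 4, with adjusted p of 0.000944 for cell adhesion, 0.511 for copper and metal response, 0.0892 for ecdysone response, 0.0680 for the Hedgehog pathway, 0.0424 for immune recognition and signalling, 0.0407 for the JAK/STAT pathway, 9.86e-16 for mitochondrial ribosomal proteins, 0.412 for ovarian somatic and germline, 0.0474 for plasmatocyte and 0.0680 for published Hox targets. Past the test in neither, axon guidance, extracellular matrix, fat body, lamellocyte, Polycomb and trithorax and pausing lists turned as well (0.507 to 0.849). With all 4 S2 libraries as 1 group it changed for cell adhesion (0.0536), immune recognition and signalling (0.962), the JAK/STAT pathway (0.893), mitochondrial ribosomal proteins (1.14e-07) and published Hox targets (0.941), and, past the test in neither, for the dosage compensation, ecdysone, Hedgehog, Polycomb and pausing lists (0.173 to 0.941). In the other alternatives it changed only for lists past the test in neither. The cause was not tested. Depth limits genes near 3 counts, and with 2 libraries per set changes near 2-fold mostly stay undetected.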

Other observations

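The gene families and single genes in this part were chosen only after the result was seen, and no test in it was planned. Other genes moved against both sets of S2 libraries. The serine protease genes psh, modSP and gd rose, psh by 5.64 on the log2 scale (SE 0.61, and 6.02 against S2 replicates 3 and 4), modSP by 2.67 (SE 0.48, and 3.91) and gd by 2.99 (SE 0.58, and 4.17). Another serine protease gene, snk, fell by 4.32 on the log2 scale but was higher in S2-AbdA than in S2 replicates 3 and 4 (2.11, adjusted p = 0.0652). The genes that rose stayed low in absolute terms, with 3.59 and 3.32 CPM of psh in the S2-AbdA libraries. The capsid-like genes Arc1 and Arc2 rose by 2.10 and 1.61, with Arc1 at 1717 and 1783 CPM in S2-AbdA against 230 to 420 in the S2 libraries. The potassium channel regulator gene Sur rose by 3.19, the septate junction gene Gli by 2.95 and the ETS factor gene Ets21C by 1.69. Among falls, Nplp2 had a log2 fold change of -2.41 (-2.89 against S2 replicates 3 and 4), with 1140 and 938 CPM in S2-AbdA against 4023 to 7619 in the S2 libraries. The calcium-binding protein gene regucalcin had -1.96 (-3.21), and Idgf3, a chitinase-like growth factor gene, -1.48 (-0.97).

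Of 45 gene families defined by symbol, tested in both directions by Fisher's exact test, the peptidoglycan recognition family stood out. Of 10 tested PGRP genes 6 fell (60.0%, against 7.30% of other genes, adjusted p = 0.00227), and 3 of them also fell against S2 replicates 3 and 4: PGRP-LA (-2.42 and -2.41), PGRP-SD (-1.77 and -1.78) and PGRP-SB1 (-2.18 and -3.03). The falling genes PGRP-LA, PGRP-LC and PGRP-LF lie side by side on 3L, while the test treats members as independent. Of 102 snoRNA genes 0 fell in edgeR's quasi-likelihood test (adjusted p = 0.0363), 5 had an unadjusted p under 0.05 with a negative value, and DESeq2, the likelihood ratio test, the exact test and limma-voom called 0, 4, 2 and 1 falls. Of 19 cuticle protein genes (Cpr) 6 fell (adjusted p = 0.0551), 1 of them against both sets. Of 10 alkaline phosphatase genes 4 fell and of 16 serpin genes (Spn) 5 fell (adjusted p = 0.0845 for each), 0 and 4 of them against both sets. Some falling members of these 3 families are also neighbours: Cpr49Ac and Cpr49Ae, the phosphatase genes CG10592 and CG5150, and Spn42Db and Spn42Dc.

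In the 3L heterochromatin 5 of 16 tested genes rose, scro, CG40472, CG40467, CG41343 and CG17374, each also against S2 replicates 3 and 4 (Fisher's exact test against all other genes, p = 7.77e-05, not adjusted for the choice). The interquartile range of their sequence's log2 fold changes was 3.33. In the X heterochromatin 4 of 11 rose (Fisher's exact test, p = 2.21e-04), 3 of them also against S2 replicates 3 and 4. Both tests treat neighbouring genes as independent.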
